A study of Arabidopsis thaliana with 14 samples.

How the data were processed

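The 14 arrays are Affymetrix ATH1 arrays of Arabidopsis thaliana, in 7 groups of 2 biological replicates: Col-0 and slr-1 at 0 h, 2 h and 6 h of 10 µM NAA, and Col-0 after 6 h of mock treatment. Per the labels' protocols, seedlings germinated on 10 µM NPA were moved to NAA at an age of 3 days, segments from above the root meristem to below the hypocotyl were pooled from about 1500 seedlings per time point, and 5.8 µg of total RNA per sample was labelled as biotinylated cRNA. The description fields of both mock samples carry text about another organism's tissue, while their source names and extraction protocols name the root segment, so both were used as Col-0 mock arrays.

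The deposited values are signal intensities made with MAS5.0, per the submitters' processing notes, and were taken as 1 unlogged intensity per probe set and array. The software's settings and target were not given in the sources used here, and detection calls were not used here. The mean after trimming 2% at each end was 1000.1 on every array. The median intensities of replicates 1 and 2 were 376.2 and 374.3 for Col-0 0 h, 365.5 and 376.4 for Col-0 2 h NAA, 383.8 and 382.1 for Col-0 6 h NAA, 382.4 and 379.4 for Col-0 6 h mock, 389.0 and 364.0 for slr-1 0 h, 366.7 and 357.2 for slr-1 2 h NAA, and 388.1 and 397.2 for slr-1 6 h NAA. The maximum of slr-1 6 h NAA replicate 2 was 29349.7, and the other arrays had maxima of 58837.1 to 124830.4. The 3' to 5' signal ratio of GAPDH was 1.16 on slr-1 0 h replicate 2 and 0.546 to 0.742 on the others. Between replicates the correlation across probe sets, which are not independent replicates, ran from 0.949 in slr-1 0 h to 0.969 in Col-0 2 h NAA.

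Of 22810 probe sets, 64 controls were left out. In the annotation table, 13513 of the remaining 22746 had 1 gene, 503 had several and 8730 had none. Probe sets were tested if the arrays of at least 1 group all exceeded the pooled 40th percentile (218.1), which left 14882, of which 8086 had 1 named gene, 300 several and 6496 none. Signals were transformed as log2 of the signal plus the pooled 10th percentile (18.9), so changes of genes with signals near or below that value are compressed by it. No further normalization was applied.

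A linear model with 1 mean per group was fitted to the 14 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean signal (7 residual and 6.57 prior degrees of freedom). From it came 11 comparisons: Col-0 2 h and 6 h NAA, and slr-1 2 h and 6 h NAA, each against 0 h; Col-0 6 h NAA against mock; mock against 0 h; 6 h against 2 h of NAA in each genotype; slr-1 against Col-0 at 0 h; and the difference of response, slr-1 minus Col-0, at 2 h and 6 h. A joint test covered the difference of response at both times. Probe sets passed at a Benjamini-Hochberg adjusted p under 0.05. Exact permutation of 2 against 2 arrays cannot give a p below 0.333 and was not used.

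Before the data were examined, 26 gene lists with 416 distinct genes were written. Of these genes 47 had a probe set of their own in the annotation table and 369 had none, and 4 lists had at least 3 tested members: Aux/IAA, GH3, lateral root regulators and cell wall loosening. After the data were examined, 30 lists based on the symbols and families that the table does name were added, 28 with at least 3 tested members. Of these, 13 passed in at least 1 comparison and 15 in none. Lists were tested with limma's camera on 1 probe set per gene at a preset correlation between genes of 0.01, with p-values adjusted over the fixed lists and over the added lists separately, and again with a correlation estimated from the arrays. The count of changed members adjusted over the list alone is given beside the count adjusted over all probe sets for the fixed lists.

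Genes to name were chosen by a rule written before the data were examined, among probe sets with 1 gene. The rule took IAA14 first, 9 genes in every comparison, per list up to 4 members with the largest change among those past the threshold, and the 10 highest rises and 10 largest falls in Col-0 6 h NAA against 0 h and in the response difference at 6 h, 5 and 5 elsewhere. Genes past the threshold had to have all differences between arrays in 1 direction. In a list with no member past the threshold, up to 2 with the highest mean signal were taken. Such members are named only for Aux/IAA, GH3 and lateral root regulators in mock against 0 h, and for DNA replication and for the G2/M phase in Col-0 2 h and slr-1 6 h. The last pair of lists had too few tested members for a list test. Members of the added lists of cytosolic ribosomal proteins, nuclear photosynthesis, mitosis and replication, nucleoli and SWEET are named only in Col-0 2 h, Col-0 6 h, 6 h NAA against mock, and slr-1 against Col-0 at 0 h. The text names part of the genes so chosen.

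The retained response is the median change in slr-1 over the probe sets called in Col-0, as a percent of the Col-0 median. Because the call and the Col-0 median share arrays, it was repeated with selection of probe sets changed at least 2-fold on arrays of 1 replicate number and measurement on the other. Counts shared by chance are products of the counts divided by the number tested. They take the calls of the compared groups as independent. All comparisons share the variance of each probe set, so an overlap above such a count is not by itself a shared response.

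The procedure was tested on simulated data, 5 runs with 200 changed genes each and the spread of these arrays. For Col-0 6 h against 0 h it recovered 62.8% of 2-fold and 93% of 4-fold changes, with 10.6 false calls per run. For the difference of response at 6 h it recovered 27.4% and 80.6%, with 7.4 false calls per run. The simulated noise was independent between genes, and 200 of 14882 is a far smaller share than was called in the data. That share was 48.6% for Col-0 6 h against 0 h and 27.5% for the response at 6 h. The rates hold for the simulated setting and are not error rates of the comparisons in the data.

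Alternatives planned before the data were examined were an added value of 1 or of the pooled 25th percentile (94.9), no filter or a filter at the pooled 60th percentile (612.8), quantile normalization, median centring, variances without trend, only the groups of a comparison in the fit, the replicate number as a block, each array left out in turn, and for lists an estimated correlation and all probe sets of a list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.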

Results

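Transcript levels were measured on 14 ATH1 arrays of Arabidopsis thaliana, in 7 groups of 2 biological replicates. The wild type Col-0 and the mutant slr-1, which carries a mutation in the Aux/IAA gene SLR/IAA14 and forms no lateral roots, were compared. Seedlings grew for 3 days on 10 µM NPA, an inhibitor of auxin transport, and then received 10 µM NAA, a synthetic auxin, for 0, 2 or 6 h. RNA came from the part of the root that lies above the meristem and below the hypocotyl, pooled from about 1500 seedlings per time point. Col-0 also had a mock treatment of 6 h. No mock arrays of slr-1 and none at 2 h were analysed here, so in those comparisons NAA and time after transfer changed together. The number of arrays limits the precision. Changes are log2 values with their standard error (SE), signals are means ± SD with n = 2, and every adjusted p comes from limma.

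IAA14 (AT4G14550), the gene mutated in slr-1, had no probe set named for it in the annotation table, so its level was not analysed here. Of the 9 genes chosen in advance to be named in every comparison, LBD16 (AT2G42430) and LBD29 (AT3G58190) had a named probe set. Over 14882 tested probe sets, the first principal component held 44.8% of the variance and the second 14.6%. The largest number of changed probe sets among the 11 comparisons was found in Col-0 after 6 h of NAA, 7225, and the smallest in slr-1 between 2 h and 6 h, 181.

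**Figure D1:**
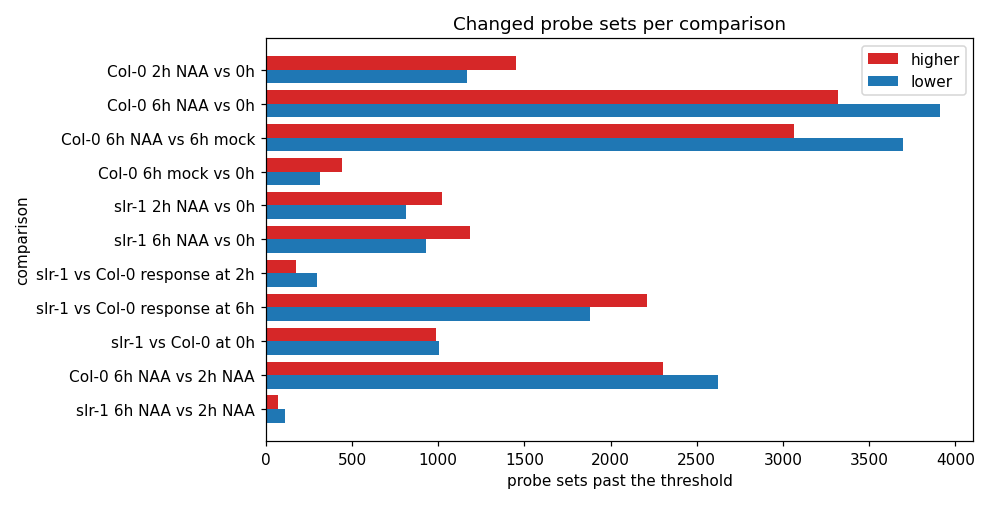
Number of probe sets past the threshold (limma, adjusted p under 0.05) in each comparison, higher in red and lower in blue, of 14882 tested. In Col-0 after 6 h of NAA 3316 were higher and 3909 lower, and in slr-1 after 6 h 1185 were higher and 931 lower.

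The first question was which genes responded early to NAA in the wild type. After 2 h in Col-0, 3 of 4 GH3 genes of auxin conjugation rose and 1 fell, and 3 of 4 Aux/IAA genes and all 3 tested lateral root regulators rose. GH3.1 (AT2G14960) rose by 7.38 (SE 0.43, adjusted p = 1.23e-07), from 8.2 ± 4.7 to 4469 ± 702. Because its signal at 0 h lay below the value of 18.9 added to every signal, the size of that change depends on the added value. LBD29 rose by 6.30 (SE 0.40, adjusted p = 2.55e-07), from 102 ± 14.8 to 9498 ± 1193. LBD16 rose by 3.22 (SE 0.17, adjusted p = 6.44e-08), from 611 ± 30.8 to 5874 ± 550.2, and PUCHI (AT5G18560) rose by 3.16 (SE 0.29, adjusted p = 6.12e-06). IAA29 rose by 3.84, GH3.3 by 4.13 and GH3.5 by 3.78, whereas GH3.17 fell by 0.90 (SE 0.19, adjusted p = 0.0046). The pair of neighbouring loci AT4G37295 and AT4G37290 rose by 6.60 and 5.91. The pectate lyase-like gene AT1G67750 rose by 4.59 and the stress-related WRKY53 (AT4G23810) by 3.19. The largest falls that kept their call without any 1 array were those of LHCB4.2 (AT3G08940), -2.78 (SE 0.34, adjusted p = 8.21e-05), and AT5G42200, -2.74 (SE 0.19, adjusted p = 6.28e-07). The replication genes MCM7 (0.04, adjusted p = 0.936) and ICU2 (-0.07, adjusted p = 0.91) did not pass the threshold. Nor did the mitotic kinases AUR1 (-0.28, adjusted p = 0.448) and AUR3 (-0.32, adjusted p = 0.662).

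By gene list, all 3 tested lateral root regulators were higher after 2 h in Col-0 (3 adjusted over the list alone, median 3.22, camera adjusted p = 1.43e-06, adjusted p = 0.00551 with an estimated correlation). Of 4 GH3 genes 3 were higher and 1 lower (3 and 1 adjusted over the list alone, median 3.96, adjusted p = 6.94e-04, adjusted p = 0.0331 with an estimated correlation). Of 4 Aux/IAA genes 3 were higher (3 adjusted over the list alone, median 2.33, adjusted p = 0.0016, adjusted p = 0.0267 with an estimated correlation). Of 6 cell wall loosening genes 3 were higher (3 adjusted over the list alone, median 0.83, adjusted p = 0.00174, adjusted p = 0.0331 with an estimated correlation), with EXPA4 (AT2G39700) at 2.75. Among 115 cytosolic ribosomal protein genes 38 were higher and 0 lower, with AT5G59240 at 3.66 and a median of 0.45 (adjusted p = 4.74e-14, adjusted p = 0.498 with an estimated correlation). Among 18 nuclear genes of photosynthesis 12 were lower and 0 higher, median -0.72 (adjusted p = 2.87e-08, adjusted p = 0.223 with an estimated correlation). In all, 1451 probe sets were higher and 1168 lower, 2619 or 17.6% of those tested, with 766 and 373 changed at least 2-fold. The total of 2619 was 1666 without Col-0 0 h replicate 1, 1512 without Col-0 0 h replicate 2, 1390 without Col-0 2 h NAA replicate 1 and 1570 without Col-0 2 h NAA replicate 2.

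**Figure D2:**
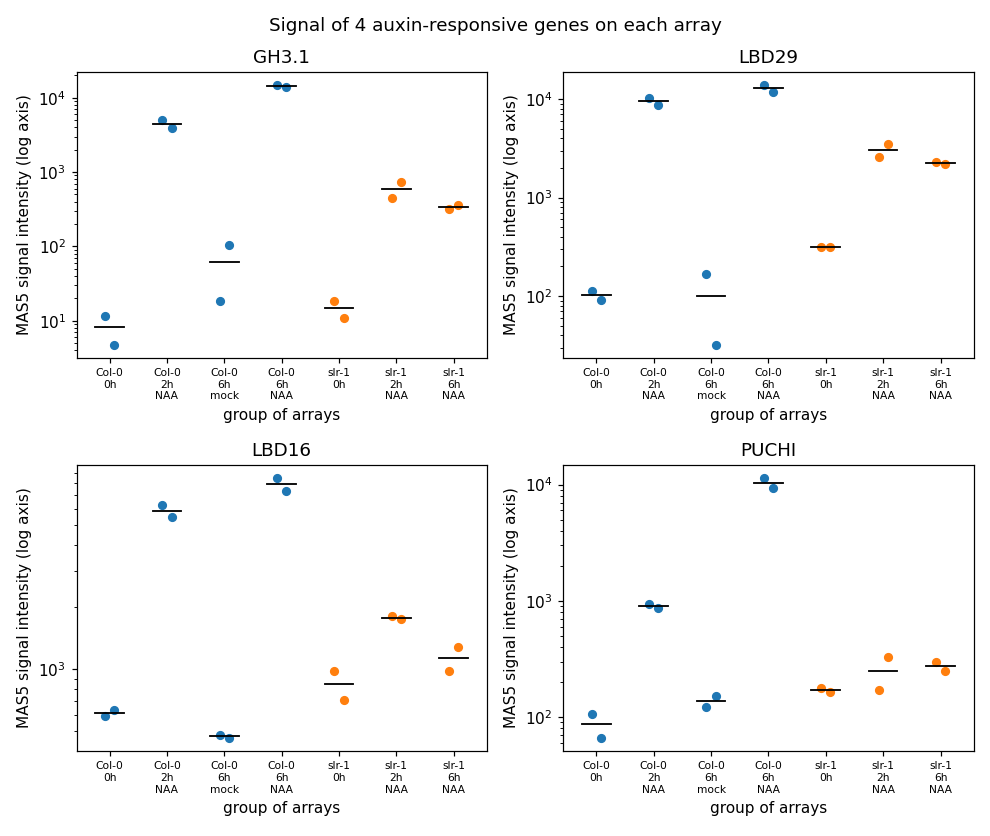
MAS5 signal intensity (log axis) of GH3.1, LBD29, LBD16 and PUCHI on each of the 14 arrays by group, Col-0 in blue and slr-1 in orange. Points are single arrays and bars are means of 2 arrays; PUCHI reached 10388 in Col-0 and 274 in slr-1 after 6 h of NAA.

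The second comparison asked how the wild type had changed after 6 h of NAA. All 4 Aux/IAA genes, 3 of 4 GH3 genes and all 3 lateral root regulators were higher than at 0 h. Of the 4 named genes of DNA replication and mitosis that had not passed at 2 h, MCM7, ICU2 and AUR1 did so and AUR3 (0.73, SE 0.42, adjusted p = 0.1685) did not. PUCHI rose by 6.64 (SE 0.29, adjusted p = 2.75e-09), from 86.7 ± 28.6 to 10388 ± 1404, and LBD29 by 6.74 (SE 0.40, adjusted p = 2.39e-08), to 12885 ± 1562. LBD16 rose by 3.66 (SE 0.17, adjusted p = 4.25e-09) to 7929 ± 784, and GH3.1 by 9.07 (SE 0.43, adjusted p = 4.1e-09) to 14374.5 ± 712. Cell wall genes were among the 10 highest rises, with the pectate lyase-like AT1G67750 at 7.81 and AT1G04680 at 6.01. AT1G30760 rose by 7.62 and the expansin EXPA4 by 4.44, to 29859 ± 3349. MCM7 rose by 2.37 (SE 0.25, adjusted p = 3.22e-06), ICU2 by 1.80 (SE 0.30, adjusted p = 2.2e-04) and AUR1 by 1.39 (SE 0.23, adjusted p = 1.7e-04). The nucleolar YAO (AT4G05410) rose by 2.52 and NRPA1 and NRPA2, subunits of RNA polymerase I, by 1.96 and 1.98. The largest fall was that of AT4G30450, -5.86 (SE 0.28, adjusted p = 4.25e-09), from 17442 ± 1457 to 303 ± 163, and its neighbour AT4G30460 changed by -4.76. The sugar transporter gene SWEET11 (AT3G48740) fell by 5.08 (SE 0.26, adjusted p = 7.86e-09), from 13078 ± 309 to 369 ± 9.1, and SWEET3 changed by -3.81. The photosynthesis genes LHCB4.2, PSAN and CHLM changed by -4.95, -3.15 and -2.81, and the auxin synthesis gene YUC6 (AT5G25620) by -3.08.

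All 115 cytosolic ribosomal protein genes were higher after 6 h of NAA in Col-0, median 1.69 with an SD of 0.68 over the genes (adjusted p = 9.21e-35, adjusted p = 0.204 with an estimated correlation). Of 10 genes of nucleoli and of polymerases I and III 8 were higher (median 1.51, adjusted p = 3.97e-05, adjusted p = 0.204 with an estimated correlation). Of 23 genes of mitosis and replication 14 were higher and 1 lower (median 1.05, adjusted p = 2.71e-04, adjusted p = 0.204 with an estimated correlation). All 18 nuclear photosynthesis genes were lower (median -1.76, adjusted p = 4.02e-09, adjusted p = 0.174 with an estimated correlation). So were 6 of 8 SWEET genes (median -1.09, adjusted p = 0.00873, adjusted p = 0.204 with an estimated correlation). Of the lists fixed in advance, 4 of 4 Aux/IAA genes were higher (4 adjusted over the list alone, median 3.61, adjusted p = 2.19e-04, adjusted p = 0.0116 with an estimated correlation). So were 3 of 4 GH3 genes (3 adjusted over the list alone, median 4.23, adjusted p = 0.00202, adjusted p = 0.0574 with an estimated correlation). All 3 lateral root regulators were higher (3 adjusted over the list alone, median 6.64, adjusted p = 2.19e-04, adjusted p = 0.0116 with an estimated correlation). The cell wall loosening list, with 2 of 6 genes higher (2 adjusted over the list alone), did not pass as a list (median 0.43, adjusted p = 0.077). Altogether 3316 probe sets were higher and 3909 lower, 7225 or 48.6% of those tested, with 2074 and 1822 changed at least 2-fold.

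Whether these changes were those of NAA or of the transfer was asked by comparing 6 h NAA with 6 h mock. GH3.1 was higher by 7.72 (SE 0.43, adjusted p = 1.52e-08), and LBD29 by 7.04 (SE 0.40, adjusted p = 2.03e-08). PUCHI was higher by 6.06 (SE 0.29, adjusted p = 6.18e-09) and LBD16 by 4.01 (SE 0.17, adjusted p = 2.88e-09). MCM7 was higher by 2.46, AUR1 by 1.49 and IAA29 by 5.27. The lowest of the changed genes relative to mock was AT4G11190, -6.81 (SE 0.38, adjusted p = 1.58e-08), at 17.8 ± 1.2 against 4118 ± 609.5. It was followed by AT4G30450 at -5.31, AT2G34610 at -5.19 and AT3G20015 at -5.11. SWEET11 differed by -3.49 (SE 0.26, adjusted p = 2.06e-07). Against mock, 114 of 115 cytosolic ribosomal protein genes were higher (median 1.39, adjusted p = 1.76e-32, adjusted p = 0.268 with an estimated correlation). All 18 nuclear photosynthesis genes were lower (median -1.56, adjusted p = 1.2e-08, adjusted p = 0.199 with an estimated correlation). Of 5 mitotic kinesins 4 were higher (median 1.60, adjusted p = 0.0285, adjusted p = 0.268 with an estimated correlation). This call ended without Col-0 6 h NAA replicate 1 (adjusted p = 0.052, range 0.00782 to 0.052 over the arrays left out). Of 33 glucosyltransferase genes (UGT) 18 were lower and 4 higher (median -0.74, adjusted p = 0.0285, adjusted p = 0.268 with an estimated correlation), a call that ended with the filter at the 60th percentile (0.0521). Part of this was a rise in mock, since the mean log2 level of UGT was 9.73 at 0 h, 10.08 after mock and 9.47 after NAA. Of 6 tetraspanin genes 5 were lower (median -0.91, adjusted p = 0.018, adjusted p = 0.239 with an estimated correlation). Kinesins, UGT and tetraspanins had not passed as lists against 0 h. Mitosis and replication (12 higher and 1 lower of 23, median 0.91, adjusted p = 2.8e-04) and nucleolar genes (8 of 10 higher, median 1.58, adjusted p = 1.24e-05) passed, each with adjusted p = 0.239 with an estimated correlation. SWEET genes passed too (6 of 8 lower, median -0.69, adjusted p = 0.0296, adjusted p = 0.268 with an estimated correlation), but not without Col-0 6 h NAA replicate 2 (adjusted p = 0.0576, range 0.0205 to 0.0576). Aux/IAA genes passed as a list (4 of 4 higher, 4 adjusted over the list alone, adjusted p = 9.66e-05, adjusted p = 0.00935 with an estimated correlation). So did GH3 genes (3 of 4 higher, 4 adjusted over the list alone, adjusted p = 2.19e-04, adjusted p = 0.0293 with an estimated correlation) and lateral root regulators (3 of 3 higher, 3 adjusted over the list alone, adjusted p = 9.66e-05, adjusted p = 0.00935 with an estimated correlation). The cell wall loosening genes, 2 higher and 1 lower (2 and 1 adjusted over the list alone), did not (median 0.07, adjusted p = 0.523). In total 3063 probe sets were higher and 3697 lower, 6760 or 45.4% of those tested. Of the 1451 probe sets higher after 2 h against 0 h, 986 were higher here too where 298.6 would be shared by chance. Of the 1168 lower ones 945 were lower where 290.2 would be.

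The change after 6 h of mock treatment against 0 h was the measure of the transfer itself. Of the named auxin genes, LBD29 (-0.29, SE 0.40, adjusted p = 0.749), LBD16 (-0.36, SE 0.17, adjusted p = 0.285), IAA29 (0.24, SE 0.28, adjusted p = 0.707), GH3.3 (-0.80, SE 0.28, adjusted p = 0.122) and GH3.5 (-0.95, SE 0.27, adjusted p = 0.0585) did not pass the threshold, but some did so in other settings. IAA29 rose without Col-0 0 h replicate 2 (0.84, adjusted p = 0.0481, range 0.0481 to 0.901 over the arrays left out). LBD29 fell without Col-0 6 h mock replicate 1 (-1.23, adjusted p = 0.0116, range 0.0116 to 0.906 over the arrays left out). GH3.3 fell without slr-1 6 h NAA replicate 1 or replicate 2 (-0.80, adjusted p = 0.0192 for each, range 0.0192 to 0.516), and with quantile normalization (-0.78, adjusted p = 0.0146). GH3.5 fell without Col-0 6 h mock replicate 2 (adjusted p = 0.0423), slr-1 0 h replicate 1 (0.0284) or replicate 2 (0.0285), or slr-1 6 h NAA replicate 1 (0.0473) or replicate 2 (0.0474), with a range of 0.0284 to 0.357. GH3.5 also fell with quantile normalization (-0.94, adjusted p = 0.0455) and with only the groups of the comparison (-0.95, adjusted p = 0.0498). The glucosyltransferase gene UGT84A1 (AT4G15480) rose 9.85-fold (log2 SE 0.51, adjusted p = 0.00314). AT4G25090 rose by 2.72 (SE 0.41, adjusted p = 0.00255), AT4G21870 by 2.62 (SE 0.37, adjusted p = 0.00185) and the cell wall gene XTH20 (AT5G48070) by 1.66 (SE 0.24, adjusted p = 0.0024). AT2G41730 fell by 2.33 (SE 0.25, adjusted p = 6.17e-04). SIS (AT5G02020) changed by -1.90 (SE 0.26, adjusted p = 0.00181) and AT5G42200, which also fell after 2 h of NAA, by -1.87 (SE 0.19, adjusted p = 6.17e-04). Of the lists added after the data were examined, 4 passed, each depending on single arrays. Cytosolic ribosomal protein genes were higher (2 of 115, median 0.27, adjusted p = 1.55e-06, adjusted p = 0.592 with an estimated correlation), but not without Col-0 6 h mock replicate 1 (adjusted p = 0.5695, range 1.71e-16 to 0.5695 over the arrays left out). Nuclear photosynthesis genes were lower (1 of 18, median -0.25, adjusted p = 0.0294, adjusted p = 0.436 with an estimated correlation), but not without Col-0 0 h replicate 2 (0.127) or Col-0 6 h mock replicate 2 (0.304), range 0.00667 to 0.304. These shifts had the direction of those with NAA and were smaller. Class III peroxidases, 7 higher and 1 lower of 35 (median 0.47, adjusted p = 0.0183, adjusted p = 0.436 with an estimated correlation), did not pass without Col-0 0 h replicate 2 (0.09, range 0.00324 to 0.09) or with the filter at the 60th percentile (0.194). The UGT genes, 7 of 33 higher (median 0.39, adjusted p = 0.0183, adjusted p = 0.436 with an estimated correlation), did not without Col-0 0 h replicate 1 (0.053) or Col-0 6 h mock replicate 2 (0.089), range 0.011 to 0.089. None of the 4 tested lists fixed in advance passed: Aux/IAA (0 genes changed, 0 adjusted over the list alone, adjusted p = 0.847), lateral root regulators (0 and 0, adjusted p = 0.847), GH3 (0, but 1 higher and 3 lower adjusted over the list alone, adjusted p = 0.262) and cell wall loosening (1 higher, 1 adjusted over the list alone, adjusted p = 0.0844). Of 756 changed probe sets, 5.08% of those tested, 443 were higher and 313 lower. That total was 471 without Col-0 0 h replicate 1, 256 without Col-0 0 h replicate 2 and 338 without Col-0 6 h mock replicate 1.

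Between 2 h and 6 h of NAA in Col-0, the question was what came late. PUCHI rose by another 3.48 (SE 0.29, adjusted p = 3.08e-06), MCM7 by 2.33 (SE 0.25, adjusted p = 1.76e-05), and ICU2 by 1.87 (SE 0.30, adjusted p = 3.8e-04). AUR1 rose by 1.67 (SE 0.23, adjusted p = 1.05e-04). PR-1-LIKE (AT2G19990) rose by 7.16 (SE 0.83, adjusted p = 3.78e-05), from 9.8 ± 6.7 to 4156 ± 1377, AT3G57950 by 5.77 and AT1G30760 by 4.79. AT4G11190 fell by 4.64 (SE 0.38, adjusted p = 2.62e-06), and AT4G30450 changed by -4.63. BCAT4 (AT3G19710), a gene of methionine chain elongation, changed by -3.14 (SE 0.51, adjusted p = 3.98e-04). WRKY53, high at 2 h, fell by 1.76 (SE 0.31, adjusted p = 6.82e-04). Of 115 cytosolic ribosomal protein genes 113 were higher (median 1.23, adjusted p = 2.14e-37, adjusted p = 0.136 with an estimated correlation). Of 23 genes of mitosis and replication 13 were higher (median 1.06, adjusted p = 2.48e-06, adjusted p = 0.136 with an estimated correlation). With the same adjusted p = 0.136 with an estimated correlation each, 8 of 10 nucleolar genes (median 1.24, adjusted p = 2.27e-06) and 3 of 5 mitotic kinesins (median 1.46, adjusted p = 0.0106) were higher. Lower, with adjusted p = 0.136 with an estimated correlation as well, were 16 of 18 nuclear photosynthesis genes (median -1.08, adjusted p = 3.82e-07) and 11 of 33 UGT genes, of which 1 was higher (median -0.44, adjusted p = 0.00126). So were 5 of 8 SWEET genes (median -0.65, adjusted p = 0.0124), 5 of 8 beta-glucosidases (median -0.87, adjusted p = 0.0173) and 2 of 4 subtilases (median -1.30, adjusted p = 0.0314), each with adjusted p = 0.136 with an estimated correlation. The last 2 did not pass with the filter at the 60th percentile (0.0511 and 0.087). The Aux/IAA list passed with 2 of 4 genes higher (3 adjusted over the list alone, median 1.05, adjusted p = 0.0227, adjusted p = 0.105 with an estimated correlation), but not without Col-0 2 h NAA replicate 2 (adjusted p = 0.0723, range 0.00589 to 0.0723 over the arrays left out). GH3 genes (2 higher, 2 adjusted over the list alone, adjusted p = 0.094), lateral root regulators (1 higher, 2 adjusted over the list alone, adjusted p = 0.0553) and cell wall loosening genes (1 higher and 2 lower, 1 and 2 adjusted over the list alone, adjusted p = 0.717) did not pass as lists. Of the 4928 changed probe sets, 33.1% of those tested, 2304 were higher and 2624 lower. The total was 3218 without Col-0 2 h NAA replicate 1 and 2956 without Col-0 6 h NAA replicate 1.

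The next question was which early responses were seen in slr-1. After 2 h, 3 of 4 GH3 genes and 2 of 3 lateral root regulators rose in the mutant. GH3.5 rose by 3.73 (SE 0.27, adjusted p = 2.68e-06), GH3.3 9.17-fold (log2 SE 0.28, adjusted p = 9.59e-06), to 39871 ± 2604. GH3.1 rose by 4.15 (SE 0.43, adjusted p = 3.59e-05), to 592 ± 203. LBD29 rose 8.98-fold (log2 SE 0.40, adjusted p = 1.84e-04), from 318 ± 0.4 to 3035 ± 638. LBD16 rose by 1.08 (SE 0.17, adjusted p = 0.00114) and IAA29 by 2.12 (SE 0.28, adjusted p = 2.25e-04). UGT84A1 rose by 4.72 (SE 0.51, adjusted p = 5.63e-05), the late embryogenesis gene LEA4-5 (AT5G06760) by 4.46 (SE 0.46, adjusted p = 3.67e-05) and AT1G16850 by 4.13 (SE 0.46, adjusted p = 6.19e-05). UGT84A1 had also risen in Col-0 after mock alone, so without mock arrays of slr-1 its rise cannot be assigned to NAA. AT3G23880 fell by 3.41 (SE 0.46, adjusted p = 2.86e-04). Of the lists, GH3 (3 of 4 higher, 3 adjusted over the list alone, median 3.46, adjusted p = 1.1e-05) and Aux/IAA (3 of 4 higher, 3 adjusted over the list alone, median 1.27, adjusted p = 0.00154) passed, each with adjusted p = 0.0184 with an estimated correlation. So did lateral root regulators (2 of 3 higher, 2 adjusted over the list alone, median 1.08, adjusted p = 0.00154, adjusted p = 0.0184 with an estimated correlation). The cell wall loosening list, with 1 gene higher (1 higher and 1 lower adjusted over the list alone), did not (adjusted p = 0.822), and its median of -0.06 differed in sign from its test. Nuclear photosynthesis genes were lower in 6 of 18 cases (median -0.39, adjusted p = 0.00653, adjusted p = 0.827 with an estimated correlation), and cytosolic ribosomal protein genes did not pass as a list (median -0.18, adjusted p = 0.0676). UGT genes were higher in 11 of 33 cases (median 0.08, adjusted p = 0.0251, adjusted p = 0.827 with an estimated correlation), but not without slr-1 0 h replicate 1 (adjusted p = 0.131, range 0.0055 to 0.131), with the filter at the 60th percentile (0.411) or with only the groups of the comparison (0.0731). Of 1832 changed probe sets, 12.3% of those tested, 1021 were higher and 811 lower. Of the 1451 higher in Col-0 after 2 h 491 were also higher in slr-1, against 99.5 by chance. Of the 1168 lower ones 379 were also lower, against 63.7. In the opposite direction 10 and 11 were shared, against 79.1 and 80.1. With Col-0 mock against 0 h, 84 of the 1021 higher in slr-1 were shared in the same direction (30.4 by chance) and 110 in the opposite (21.5 by chance). Of the 811 lower ones 49 were shared in the same direction (17.1 by chance) and 73 in the opposite (24.1 by chance). Without slr-1 2 h NAA replicate 1 the total was 800 and without slr-1 0 h replicate 2 it was 1100.

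After 6 h of NAA in slr-1, 3 of 4 GH3 and 3 of 4 Aux/IAA genes were higher than at 0 h. Of the cell cycle genes fixed in advance, none passed over all probe sets, but both tested DNA replication genes were higher when adjusted over the list alone (2 of 2, median 0.62). Of the G2/M genes 0 of 2 were. GH3.1 was higher by 3.42 (SE 0.43, adjusted p = 2.44e-04), GH3.5 by 2.86, GH3.3 by 2.46, IAA29 by 2.45 (SE 0.28, adjusted p = 1.22e-04) and EXPA4 by 1.37 (SE 0.27, adjusted p = 0.00453). LBD29 was higher by 2.76 (SE 0.40, adjusted p = 6.66e-04), at 2258 ± 92.3. LBD16 (0.42, SE 0.17, adjusted p = 0.126), MCM7 (0.57, SE 0.25, adjusted p = 0.145), ICU2 (0.67, SE 0.30, adjusted p = 0.16), AUR1 (-0.21, SE 0.23, adjusted p = 0.592) and AUR3 (-0.46, SE 0.42, adjusted p = 0.508) did not pass. Without slr-1 0 h replicate 1 LBD16 passed (0.65, adjusted p = 0.0378, range 0.0378 to 0.539 over the arrays left out). AT5G62210 rose by 4.79 (SE 0.94, adjusted p = 0.0042), UGT84A1 by 4.39 (SE 0.51, adjusted p = 1.53e-04) and AT2G22590 by 4.03 (SE 0.36, adjusted p = 2.39e-05). AT1G19530 fell by 2.79 (SE 0.27, adjusted p = 4.99e-05) and TBL41 (AT3G14850) changed by -2.60 (SE 0.51, adjusted p = 0.00434). The lists of Aux/IAA (3 of 4 higher, 3 adjusted over the list alone, median 1.46, adjusted p = 2.66e-04, adjusted p = 0.0242 with an estimated correlation) and GH3 (3 of 4 higher, 3 adjusted over the list alone, median 2.66, adjusted p = 2.66e-04, adjusted p = 0.0361 with an estimated correlation) passed. Lateral root regulators passed with 1 of 3 genes higher (2 adjusted over the list alone, median 0.62, adjusted p = 0.0176, adjusted p = 0.0556 with an estimated correlation), but not without slr-1 0 h replicate 2 (adjusted p = 0.063, range 0.00473 to 0.063 over the arrays left out). Cell wall loosening did not pass (1 higher, 1 adjusted over the list alone, median 0.21, adjusted p = 0.479), and cytosolic ribosomal protein genes did not either (4 higher and 1 lower of 115, median 0.13, adjusted p = 0.207). Nuclear photosynthesis genes were lower in 4 of 18 cases (median -0.26, adjusted p = 0.0318, adjusted p = 0.588 with an estimated correlation), but not without slr-1 6 h NAA replicate 2 (adjusted p = 0.103, range 0.00276 to 0.103). UGT genes were higher in 13 of 33 cases (median 0.26, adjusted p = 0.0477, adjusted p = 0.588 with an estimated correlation). That call ended without slr-1 0 h replicate 1 (0.145), slr-1 6 h NAA replicate 1 (0.0933), Col-0 0 h replicate 1 (0.0564) or replicate 2 (0.0571), or Col-0 2 h NAA replicate 1 (0.0512) or replicate 2 (0.0521), with a range of 0.0246 to 0.145. It ended as well with an added value at the 25th percentile (0.0513), the filter at the 60th percentile (0.217) and a replicate block (0.0545). Of 2116 changed probe sets, 14.2% of those tested, 1185 were higher and 931 lower, a balance that turned to 967 and 1226 with each array centred on its median. Of the higher ones 607 were among the 3316 higher in Col-0, against 264 by chance, and of the lower ones 715 were also lower there, against 244.5. With Col-0 mock against 0 h, 122 of the higher ones were shared in the same direction (35.3 by chance) and 71 in the opposite (24.9 by chance). Of the lower ones 75 were shared in the same direction (19.6 by chance) and 55 in the opposite (27.7 by chance). The total was 1155 without slr-1 6 h NAA replicate 1 and 1383 without slr-1 6 h NAA replicate 2.

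**Figure D3:**
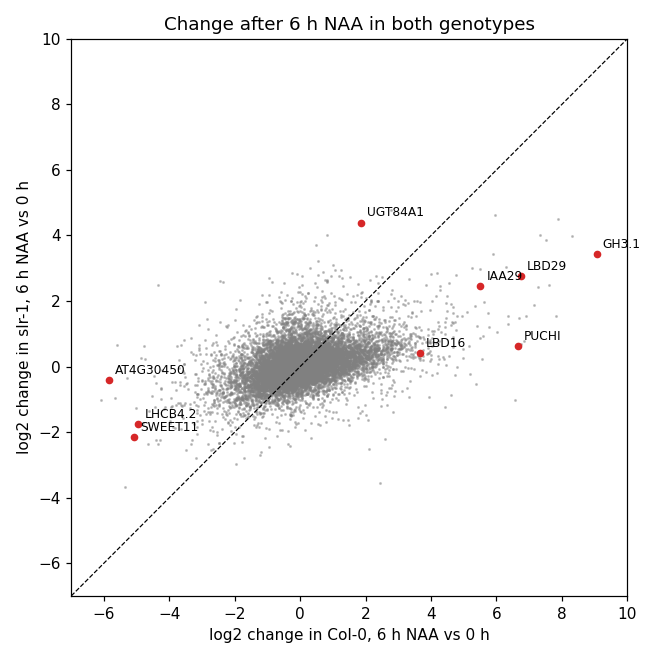
Log2 change after 6 h of NAA against 0 h in slr-1 (vertical axis) and in Col-0 (horizontal axis), 1 grey point for each of 14882 probe sets, with some named genes in red and a dashed line of equal change. The correlation across probe sets, which are not independent replicates, was 0.443.

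Between 2 h and 6 h of NAA in slr-1, fewer probe sets passed than in any other of the 11 comparisons. AT4G18280 fell by 2.76 (SE 0.29, adjusted p = 8.17e-04), and AT5G44020 changed by -2.42 (SE 0.31, adjusted p = 0.00302). AT2G23120 changed by -1.87 (SE 0.20, adjusted p = 9.74e-04), from 28491 ± 701 to 7794 ± 841, and AT1G05340 by -1.83 (SE 0.19, adjusted p = 8.17e-04). The GH3 list was lower (0 genes by themselves, 2 lower adjusted over the list alone, median -0.73, adjusted p = 0.0412, adjusted p = 0.277 with an estimated correlation). This call ended without slr-1 2 h NAA replicate 2 (adjusted p = 0.3) and without slr-1 6 h NAA replicate 2 (adjusted p = 0.168), with a range of 0.0107 to 0.3 over the arrays left out. Aux/IAA (0 changed, 0 adjusted over the list alone, adjusted p = 0.229), lateral root regulators (0 changed, 1 lower adjusted over the list alone, adjusted p = 0.229) and cell wall loosening (0 and 0, adjusted p = 0.365) did not pass. Both tested DNA replication genes were higher when adjusted over the list alone (2 of 2, median 0.99). Of the added lists, cytosolic ribosomal protein genes were higher (0 of 115 by themselves, median 0.29, adjusted p = 4.68e-08, adjusted p = 0.772 with an estimated correlation), but not without slr-1 6 h NAA replicate 1 (adjusted p = 0.0953, range 8.78e-15 to 0.0953). Class III peroxidases were lower (2 of 35, median -0.11, adjusted p = 0.0124, adjusted p = 0.772 with an estimated correlation), but not without slr-1 6 h NAA replicate 2 (adjusted p = 0.268, range 0.00148 to 0.268) or with quantile normalization (0.163). limma called 69 probe sets higher and 112 lower (49 and 164 with each array centred on its median), 181 or 1.22% of those tested, and 2287 had an unadjusted p under 0.05. The total was 30 without slr-1 2 h NAA replicate 1, 58 without slr-1 2 h NAA replicate 2, 77 without slr-1 6 h NAA replicate 1 and 53 without slr-1 6 h NAA replicate 2.

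Whether the response to NAA differed between the genotypes was tested as a difference of changes, slr-1 minus Col-0. At 2 h the response of PUCHI was lower in slr-1 (-2.73, SE 0.41, adjusted p = 0.00401), and that of LBD16 (-2.15, SE 0.25, adjusted p = 7.34e-04) was too. The difference was -4.35 for AT1G67750 (SE 0.57, adjusted p = 0.00197) and -3.34 for the endoglucanase gene GH9B13 (AT4G02290) (SE 0.44, adjusted p = 0.00197). AT3G17110 had an 8.58-fold higher response in slr-1 (log2 SE 0.55, adjusted p = 0.00855), and AT1G69080 one higher by 2.67 (SE 0.48, adjusted p = 0.00978). All 3 lateral root regulators had a lower response (3 adjusted over the list alone, median -2.73, adjusted p = 3.94e-06, adjusted p = 0.00687 with an estimated correlation). So had 2 of 6 cell wall loosening genes (3 adjusted over the list alone, median -1.51, adjusted p = 5.63e-04, adjusted p = 0.0362 with an estimated correlation). The levels of the 6 at 2 h of NAA were close in both genotypes (median -0.21, slr-1 minus Col-0), while at 0 h the median difference was 1.12, with 3 of 6 genes higher (list adjusted p = 0.00214, adjusted p = 0.0885 with an estimated correlation). The difference did not pass for Aux/IAA (1 lower, 1 adjusted over the list alone, adjusted p = 0.108) or GH3 (1 higher and 1 lower, 1 and 2 adjusted over the list alone, adjusted p = 0.375). Of 473 probe sets 176 had a higher and 297 a lower response, 3.18% of those tested. The total was 243 without Col-0 2 h NAA replicate 1, 195 without Col-0 2 h NAA replicate 2, 284 without Col-0 0 h replicate 2, 157 without slr-1 2 h NAA replicate 1, 831 without slr-1 0 h replicate 1 and 283 without slr-1 0 h replicate 2.

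At 6 h the lists of lateral root regulators and Aux/IAA and single genes of the cell wall and cell cycle differed in response. Of the cell cycle genes fixed in advance, 1 of 2 of DNA replication (2 adjusted over the list alone) and 1 of 2 of the G2/M phase (1 adjusted over the list alone) had a lower response. PUCHI differed by -6.02 (SE 0.41, adjusted p = 1.74e-06), GH3.1 by -5.64 (SE 0.60, adjusted p = 2.92e-05), and LBD29 by -3.98 (SE 0.57, adjusted p = 2.2e-04). LBD16 differed by -3.23 (SE 0.25, adjusted p = 3.44e-06) and IAA29 by -3.05 (SE 0.39, adjusted p = 1.13e-04). The cell cycle genes MCM7 (-1.81, SE 0.35, adjusted p = 0.00179) and AUR1 (-1.60, SE 0.32, adjusted p = 0.00229) responded less in slr-1. So did the cell wall genes AT1G67750 (-6.28, SE 0.57, adjusted p = 1.02e-05), AT1G04680 (-4.96, SE 0.27, adjusted p = 4.46e-07) and EXPA4 (-3.07, SE 0.38, adjusted p = 9.17e-05). Of 2210 probe sets with a higher difference, 1788 were called lower in Col-0. Genes that fell in Col-0 and had a higher difference included AT4G30450 (5.44, SE 0.40, adjusted p = 2.37e-06), AT4G30460 (5.40, SE 0.37, adjusted p = 1.74e-06), AT3G20015 (4.98, SE 0.37, adjusted p = 2.37e-06) and YUC6 (3.45, SE 0.76, adjusted p = 0.00452). The largest higher difference among named genes belonged to OCT1 (AT1G73220), 6.82 (SE 0.60, adjusted p = 7.54e-06). Of 115 cytosolic ribosomal protein genes 112 responded less in slr-1 (median -1.55, adjusted p = 8.41e-41, adjusted p = 0.151 with an estimated correlation). All 18 nuclear photosynthesis genes had a higher difference (median 1.49, adjusted p = 3.55e-09, adjusted p = 0.151 with an estimated correlation). At 0 h their median level, slr-1 minus Col-0, was -1.11, and at 6 h of NAA it was 0.32.

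Lateral root regulators (3 of 3 lower at 6 h, 3 adjusted over the list alone, median -3.98, adjusted p = 8.98e-05, adjusted p = 0.015 with an estimated correlation) and Aux/IAA genes (2 of 4 lower, 4 adjusted over the list alone, median -2.15, adjusted p = 0.0014, adjusted p = 0.0216 with an estimated correlation) passed as lists. GH3 genes passed too (3 of 4 lower, 3 adjusted over the list alone, median -1.57, adjusted p = 0.019, adjusted p = 0.131 with an estimated correlation), but not without slr-1 0 h replicate 1 (adjusted p = 0.0648, range 0.00858 to 0.0648 over the arrays left out). Cell wall loosening did not pass (1 lower, 1 adjusted over the list alone, median -0.47, adjusted p = 0.0695). The 4092 probe sets with a different response at 6 h, 27.5% of those tested, had a higher value in 2210 cases and a lower one in 1882, a balance that turned to 1858 and 2070 with each array centred on its median. A joint test of both time points called 3377 probe sets, and 2107 without Col-0 6 h NAA replicate 1.

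How much of the wild-type response slr-1 retained was measured as a median over the genes called in Col-0, with the SD between replicate numbers (n = 2). For the 1451 probe sets higher after 2 h the median change was 1.04 ± 0.01 in Col-0 and 0.42 ± 0.02 in slr-1, 40.2%. For the 1168 lower ones it was -0.83 ± 0.02 and -0.46 ± 0.01, 55.4%. After 6 h the 3316 higher ones had 1.24 ± 0.07 in Col-0 and 0.29 ± 0.02 in slr-1, 23.5%, and the 3909 lower ones -0.96 ± 0.04 and -0.23 ± 0.06, 24.4%. With probe sets selected on arrays of 1 replicate number and measured on those of the other, these shares were 42.5%, 60.6%, 23.5% and 26.5%.

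**Figure D4:**
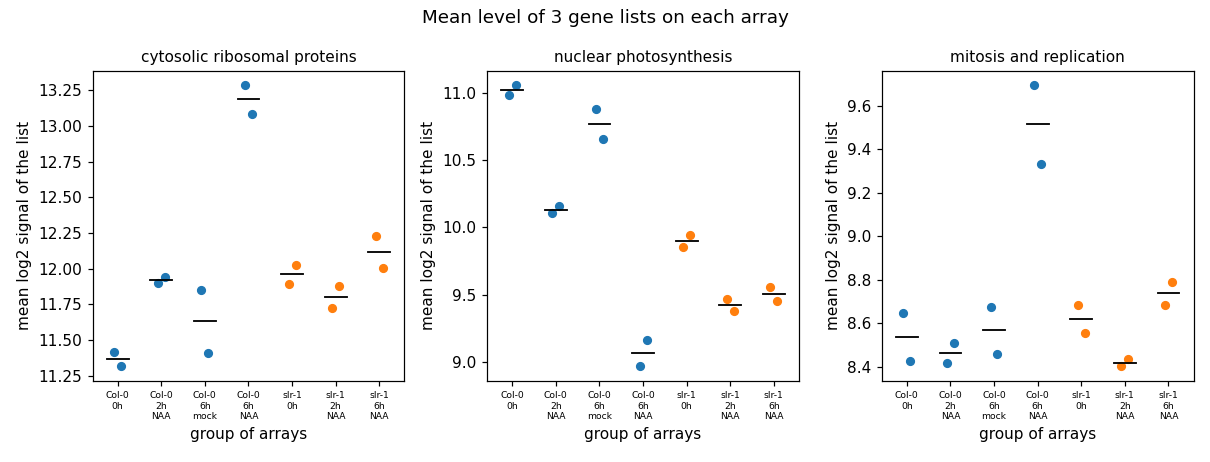
Mean log2 signal of the tested genes of 3 lists on each array by group, Col-0 in blue and slr-1 in orange, bars being means of 2 arrays. Cytosolic ribosomal protein genes reached 13.19 in Col-0 and 12.12 in slr-1 after 6 h of NAA.

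The last comparison asked how the genotypes differed before NAA. At 0 h, BCAT4 was 17.2-fold higher in slr-1 (log2 SE 0.51, adjusted p = 3.08e-04), at 22386 ± 622 against 1395 ± 775. CYP71B5 (AT3G53280) was higher by 4.54 (SE 0.76, adjusted p = 0.00201), AT4G12490 by 4.08 (SE 0.37, adjusted p = 3.07e-05), AT5G44400 by 3.85 and AT4G25090 by 3.84. SWEET11 had a difference of -3.50 (SE 0.26, adjusted p = 1.72e-05), at 1137 ± 79.7 in slr-1 against 13078 ± 309 in Col-0. AT3G54580 had one of -3.07 (SE 0.49, adjusted p = 0.00136) and RCA (AT2G39730) of -1.67 (SE 0.19, adjusted p = 1.61e-04). Nuclear photosynthesis genes were lower in slr-1 in 16 of 18 cases (median -1.11, adjusted p = 1.86e-14, adjusted p = 0.0494 with an estimated correlation), among them LHCB4.2 at -2.08. Cytosolic ribosomal protein genes were higher in 54 of 115 cases (median 0.62, adjusted p = 3.51e-21, adjusted p = 0.581 with an estimated correlation). Cell wall loosening genes were higher in 3 of 6 cases (5 adjusted over the list alone, median 1.12, adjusted p = 0.00214, adjusted p = 0.0885 with an estimated correlation), among them XTH20 at 1.26 (SE 0.24, adjusted p = 0.00477). Pectate lyase-like genes were higher in 5 of 13 cases (median 0.24, adjusted p = 0.0285, adjusted p = 0.539 with an estimated correlation), but not without slr-1 0 h replicate 2 (adjusted p = 0.137, range 0.0148 to 0.137). Lateral root regulators were higher as a list (1 of 3, 3 adjusted over the list alone, median 0.88, adjusted p = 0.0334, adjusted p = 0.0945 with an estimated correlation), but not without Col-0 0 h replicate 2 (adjusted p = 0.0753) or slr-1 0 h replicate 1 (adjusted p = 0.174), with a range of 0.00817 to 0.174. Aux/IAA (1 higher, 1 adjusted over the list alone, adjusted p = 0.91) and GH3 (1 higher, 1 higher and 2 lower adjusted over the list alone, adjusted p = 0.91) did not pass. Of 1994 changed probe sets, 13.4% of those tested, 987 were higher and 1007 lower in slr-1. The total was 1154 without Col-0 0 h replicate 1, 860 without Col-0 0 h replicate 2 and 1002 without slr-1 0 h replicate 2.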

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

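Of the tests below, those on a higher starting level in slr-1, on time and handling after transfer, on the spread of the slr-1 arrays and on single pairs of slr-1 arrays were chosen only after the result was seen, and so were the lists added after the data were examined. p-values here measure only the spread between these samples.

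The results in this part stand out because the response to NAA differed between the genotypes by a test of the difference itself. At 2 h 473 probe sets differed, at 6 h 4092, and over both times 3377. The number at 2 h was 243 without Col-0 2 h NAA replicate 1, 195 without Col-0 2 h NAA replicate 2, 284 without Col-0 0 h replicate 2, 831 without slr-1 0 h replicate 1, 283 without slr-1 0 h replicate 2 and 157 without slr-1 2 h NAA replicate 1. The number over both times was 2107 without Col-0 6 h NAA replicate 1.

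Among lists at 2 h, the response in slr-1 was lower for lateral root regulators (median difference -2.73), cell wall loosening (-1.51), cytosolic ribosomal proteins (-0.67, adjusted p = 0.411 with an estimated correlation) and pectate lyase-like genes (-0.38, adjusted p = 0.394 with an estimated correlation), and higher for nuclear photosynthesis (0.39, adjusted p = 0.394 with an estimated correlation). The levels at 2 h of NAA, slr-1 minus Col-0, were close for cell wall loosening (median -0.21), ribosomal proteins (-0.05) and pectate lyase-like genes (-0.06), with median differences of 1.12, 0.62 and 0.24 at 0 h, so by these medians most of the lower response lay in the level at 0 h. The list calls at 0 h were lost for cell wall loosening (adjusted p = 0.0885 with an estimated correlation), ribosomal proteins (adjusted p = 0.581 with an estimated correlation) and pectate lyase-like genes (adjusted p = 0.539 with an estimated correlation). That of pectate lyase-like genes also ended without slr-1 0 h replicate 2 (0.137, range 0.0148 to 0.137). For lateral root regulators the level at 2 h was itself lower in slr-1 (3 of 3, median -1.71). Nuclear photosynthesis genes, with the higher response, were lower in slr-1 at 0 h (median -1.11) and still at 2 h of NAA (8 of 18, median -0.80). At 6 h the response was lower for Aux/IAA (-2.15), lateral root regulators (-3.98), GH3 (-1.57, adjusted p = 0.131 with an estimated correlation) and mitotic kinesins (-1.63, adjusted p = 0.19 with an estimated correlation). With adjusted p = 0.151 with an estimated correlation each, it was also lower for cytosolic ribosomal proteins (-1.55), pectate lyase-like genes (-1.73), mitosis and replication (-0.75) and nucleolar genes (-1.27). It was higher for nuclear photosynthesis (1.49), glucosyltransferases (0.88), beta-glucosidases (1.202) and tetraspanins (0.92), each with adjusted p = 0.151 with an estimated correlation, and for SWEET genes (0.90, adjusted p = 0.183 with an estimated correlation). The median level at 6 h of NAA, slr-1 minus Col-0, was 0.32 for nuclear photosynthesis and 0.34 for SWEET genes. Both lists were lower in slr-1 at 0 h (median -1.11 for nuclear photosynthesis, mean log2 level 9.69 against 10.55 for SWEET). By these values most of their higher response lay in the level at 0 h. The level at 6 h differed more for glucosyltransferases (0.72), beta-glucosidases (0.87) and tetraspanins (0.57). By adjusted p, these list calls at 6 h ended when single arrays were left out: GH3 without slr-1 0 h replicate 1 (0.0648) (range 0.00858 to 0.0648) and pectate lyase-like without slr-1 0 h replicate 2 (0.0547) (range 0.0143 to 0.0547). The same happened to mitotic kinesins without Col-0 6 h NAA replicate 1 (0.0664), slr-1 6 h NAA replicate 1 (0.0601), slr-1 0 h replicate 2 (0.0709) (range 0.00654 to 0.0709) and to beta-glucosidases without Col-0 2 h NAA replicate 1 (0.0565) and replicate 2 (0.0568), Col-0 6 h NAA replicate 2 (0.051), slr-1 0 h replicate 1 (0.0661) (range 0.0218 to 0.0661). With the filter at the 60th percentile the calls of glucosyltransferases (0.0677), beta-glucosidases (0.0625) and tetraspanins (0.0744) ended, and with only the groups of the comparison that of beta-glucosidases (0.0537) did.

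Among genes at 2 h, the response in slr-1 was lower for LBD29 (-3.14), LBD16 (-2.15), PUCHI (-2.73), IAA29 (-1.71), GH3.1 (-3.23), AT3G05060 (-1.33), XTH18 (-2.04), EXPA4 (-1.67), AT1G67750 (-4.35), AT1G21060 (-4.33) and GH9B13 (-3.34). It was higher for GH3.17 (1.10), AT3G17110 (3.101), OCT1 (2.84), LEA4-5 (2.84), AT1G69080 (2.67) and AT1G24600 (2.63). The calls of LBD16, PUCHI, AT1G67750, GH9B13, AT3G17110 and AT1G69080 held with each single array left out. The other calls ended, at these adjusted p-values, for LBD29 without slr-1 2 h NAA replicate 1 (0.0528) (range 0.000191 to 0.0528), for GH3.1 without Col-0 2 h NAA replicate 1 (0.0517), slr-1 2 h NAA replicate 1 (0.0617) (range 0.000993 to 0.0617) and for IAA29 without Col-0 2 h NAA replicate 1 (0.0891) and replicate 2 (0.0966), slr-1 2 h NAA replicate 1 (0.117) and replicate 2 (0.0556), slr-1 0 h replicate 2 (0.0688) (range 0.00101 to 0.117). XTH18 lost its call without Col-0 0 h replicate 2 (0.0805), Col-0 2 h NAA replicate 2 (0.102), slr-1 2 h NAA replicate 1 (0.0732) and replicate 2 (0.0542), slr-1 0 h replicate 2 (0.0699) (range 0.00675 to 0.102). EXPA4 lost its call without Col-0 0 h replicate 1 (0.0562) and replicate 2 (0.111), Col-0 2 h NAA replicate 2 (0.142), slr-1 0 h replicate 1 (0.0643), slr-1 2 h NAA replicate 1 (0.0953) and replicate 2 (0.0715) (range 0.0177 to 0.142). AT3G05060 lost its call without Col-0 0 h replicate 1 (0.0538) and replicate 2 (0.0558), Col-0 2 h NAA replicate 1 (0.0504) and replicate 2 (0.0876), slr-1 2 h NAA replicate 1 (0.0644) and replicate 2 (0.0574) (range 0.000849 to 0.0876). AT1G21060 lost its call without Col-0 2 h NAA replicate 1 (0.104) and replicate 2 (0.0649), Col-0 0 h replicate 2 (0.0502), slr-1 2 h NAA replicate 1 (0.0508) and replicate 2 (0.0527), slr-1 0 h replicate 2 (0.0619) (range 0.0114 to 0.104). GH3.17 lost its call without Col-0 0 h replicate 1 (0.0979) and replicate 2 (0.101), Col-0 2 h NAA replicate 1 (0.104) and replicate 2 (0.121), slr-1 2 h NAA replicate 1 (0.106) and replicate 2 (0.0973), slr-1 0 h replicate 2 (0.127) (range 0.0134 to 0.127). OCT1 lost its call without Col-0 0 h replicate 1 (0.0713), Col-0 2 h NAA replicate 1 (0.0675) and replicate 2 (0.0635), slr-1 2 h NAA replicate 1 (0.0572) and replicate 2 (0.0622) (range 0.0112 to 0.0713). LEA4-5 lost its call without Col-0 0 h replicate 1 (0.107), Col-0 2 h NAA replicate 1 (0.0843) and replicate 2 (0.105), slr-1 2 h NAA replicate 1 (0.15), slr-1 0 h replicate 2 (0.105) (range 0.017 to 0.15). AT1G24600 lost its call without Col-0 0 h replicate 1 (0.0505) and replicate 2 (0.163), Col-0 2 h NAA replicate 1 (0.0843) and replicate 2 (0.158), Col-0 6 h NAA replicate 1 (0.0538) and replicate 2 (0.0522), slr-1 0 h replicate 1 (0.0801), slr-1 2 h NAA replicate 1 (0.184), slr-1 6 h NAA replicate 1 (0.0539) and replicate 2 (0.0556) (range 0.0333 to 0.184).

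Among genes at 6 h, the response in slr-1 was lower for LBD29 (-3.98), LBD16 (-3.23), PUCHI (-6.02), IAA29 (-3.05), IAA18 (-0.86), GH3.1 (-5.64), GH3.3 (-1.81), GH3.5 (-1.33), MCM7 (-1.81), AUR1 (-1.60), AT3G05060 (-2.29) and EXPA4 (-3.07). It was also lower for AT1G67750 (-6.28), AT3G59850 (-5.92), AT1G30760 (-5.14), AT2G03740 (-4.98), AT1G04680 (-4.96), AT1G05577 (-4.82), PR-1-LIKE (-4.81) and AT3G06990 (-4.78). It was higher for YUC6 (3.45), GSO1 (1.18), RCA (1.38), OCT1 (6.82), AT4G30450 (5.44), AT4G30460 (5.40), AT1G20030 (5.08), AT3G20015 (4.98), AT2G34610 (4.97), AT3G17110 (4.89), AT2G40460 (4.39), scpl31 (4.37) and AT5G19730 (4.31). By adjusted p, IAA18 lost its call without Col-0 6 h NAA replicate 1 (0.0778), Col-0 0 h replicate 2 (0.0626), slr-1 6 h NAA replicate 2 (0.0559) (range 0.0114 to 0.0778). GH3.5 lost its call without Col-0 6 h NAA replicate 1 (0.0648), Col-0 0 h replicate 2 (0.0649), slr-1 0 h replicate 1 (0.0744), slr-1 6 h NAA replicate 2 (0.0877) (range 0.00414 to 0.0877). AT1G05577 lost its call without Col-0 6 h NAA replicate 1 (0.0673) (range 0.00734 to 0.0673). PR-1-LIKE lost its call without Col-0 6 h NAA replicate 1 (0.0541) (range 0.00202 to 0.0541). The other calls named here held with each single array left out.

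Cytosolic ribosomal protein genes rose in Col-0 by 6 h of NAA (115 of 115, as a list adjusted p = 0.204 with an estimated correlation) and did not pass as a list in slr-1 at 6 h against 0 h, with a median difference of response of -1.55 over 115 genes. Compressed high signals on slr-1 6 h NAA replicate 2 are argued against as the whole cause, since without that array the median was -1.42. Scaling or saturation of all abundant probe sets is argued against too: 0% of 10000 random lists matched on mean signal had a median as low, and their medians ran from -0.14 to 0.41. A higher starting level in slr-1 leaves a gap to be explained, since at 6 h the level in slr-1 was still below that of Col-0 (median -0.93), and time and handling leave the rise over mock (median 1.39). An effect of the slr-1 mutation on this rise is a candidate explanation. It was found on these same data, and how SLR/IAA14 would act in it was not tested. With the correlation between the genes estimated from the arrays (0.487) the list's camera adjusted p was 0.151.

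Few probe sets changed in slr-1 between 2 h and 6 h: limma called 181, a number that depended on single arrays, as given above. For a larger spread of the slr-1 arrays, the ratio of pooled SDs, slr-1 to Col-0, was 1.07. This ratio cannot decide the question, because the model shares the variance of each probe set over all groups. The median SE of 6 h against 2 h was 0.2144 in Col-0 and 0.2144 in slr-1. Changes of the same size that missed the threshold are argued against for genes that rose in Col-0: over genes 2-fold higher on one Col-0 replicate number (in place of genes called in Col-0, as first planned) the slr-1 median was 27.5% of the Col-0 median, and 23.3% to 33.4% over 8 combinations of arrays, all below the 50% set in advance as needed. The 27.5% was not below the 25% set in advance as excluding it, and reading all combinations under 50% as enough was decided after the result was seen. Compressed high signals on slr-1 6 h NAA replicate 2 are argued against as the whole cause for these genes by the same reading. Their share was 25.4% to 33.4% over the 4 combinations without that array, below 50% but not below 25%. Over probe sets called higher in Col-0 the share was 29.5% on the slr-1 replicate 1 arrays. There the call and the Col-0 median share arrays, which can raise that median and lower the share, so the 29.5% adds little. Smaller changes that missed the threshold stay open, and without mock arrays of slr-1, not analysed here, the design does not separate time from NAA.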

How the results depend on the processing

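The alternatives were planned before the data were examined, except the added lists, which were chosen after seeing the data. Counts of changed probe sets moved by more than 1.5 times in few settings. Without a trend in the variances they were 481 for mock against 0 h (main 756), 273 for the response at 2 h (473) and 75 for slr-1 6 h against 2 h (181). With only the groups of a comparison in the fit they were 453 for mock against 0 h, 1068 for slr-1 2 h (1832), 1367 for slr-1 6 h (2116) and 1205 for slr-1 against Col-0 at 0 h (1994). The cause was not tested.

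Leaving out single arrays gave the widest ranges, and the lone array left in a group is then assumed to vary like the other groups. The counts ran from 1390 (without Col-0 2 h NAA replicate 1) to 2863 for Col-0 2 h, and were 1666 without Col-0 0 h replicate 1, 1512 without Col-0 0 h replicate 2 and 1570 without Col-0 2 h NAA replicate 2. They ran from 5444 to 7534 for Col-0 6 h, from 5011 to 7073 for 6 h NAA against mock and from 2795 to 4128 for the response at 6 h. For mock against 0 h they ran from 256 (without Col-0 0 h replicate 2) to 874, with 471 without Col-0 0 h replicate 1 and 338 without mock replicate 1. For slr-1 2 h they ran from 800 (without slr-1 2 h NAA replicate 1) to 2041, with 1100 without slr-1 0 h replicate 2. For slr-1 6 h they ran from 1155 (without slr-1 6 h NAA replicate 1) to 2207, with 1383 without slr-1 6 h NAA replicate 2. For slr-1 against Col-0 at 0 h they ran from 860 (without Col-0 0 h replicate 2) to 2088, with 1154 without Col-0 0 h replicate 1 and 1002 without slr-1 0 h replicate 2. For Col-0 6 h against 2 h they ran from 2956 (without Col-0 6 h NAA replicate 1) to 5244, with 3218 without Col-0 2 h NAA replicate 1. The range was 157 (without slr-1 2 h NAA replicate 1) to 831 (without slr-1 0 h replicate 1) for the response at 2 h, with 243 without Col-0 2 h NAA replicate 1, 195 without Col-0 2 h NAA replicate 2, 284 without Col-0 0 h replicate 2 and 283 without slr-1 0 h replicate 2. It was 30 (without slr-1 2 h NAA replicate 1) to 233 for slr-1 6 h against 2 h, with 58 without slr-1 2 h NAA replicate 2, 77 without slr-1 6 h NAA replicate 1 and 53 without slr-1 6 h NAA replicate 2, and 2107 (without Col-0 6 h NAA replicate 1) to 3620 for the joint test.

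The number of the 4 tested fixed lists that passed changed in several comparisons. With an estimated correlation it was 2 instead of 3 in Col-0 6 h, where GH3 no longer passed, in slr-1 6 h, where lateral root regulators did not, and in the response at 6 h, where GH3 did not. In mock against 0 h, where none passed, 1 passed without a filter, 1 with a filter at the pooled 60th percentile and 0 to 1 with single arrays left out. At 0 h, 0 passed with an estimated correlation and 1 to 2 with single arrays left out. In Col-0 6 h against 2 h, 2 passed with an added value at the pooled 25th percentile, 2 without a filter, 0 with a filter at the pooled 60th percentile, 3 with only its own groups, 0 with an estimated correlation and 0 to 2 with single arrays left out. In slr-1 6 h against 2 h, 0 passed with an added value of 1, a filter at the pooled 60th percentile, quantile normalization, median centring or an estimated correlation, and 0 to 1 with single arrays left out. With single arrays left out, 2 to 3 passed in slr-1 6 h and in the response at 2 h, and 2 to 4 in the response at 6 h.

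Signs turned only for genes that had not passed. In Col-0 2 h, ICU2 was 0.0419 with quantile normalization, 0.06 without Col-0 0 h replicate 1 and 0.15 without Col-0 2 h NAA replicate 1 (range -0.28 to 0.15 over the arrays left out). MCM7 was -0.10 without Col-0 2 h NAA replicate 1 and -0.06 without Col-0 0 h replicate 2 (range -0.10 to 0.18). In mock against 0 h, LBD29 was 0.64 without mock replicate 2 (range -1.23 to 0.64), IAA18 0.13 without mock replicate 1 (range -0.32 to 0.13) and IAA29 -0.365 without Col-0 0 h replicate 1 (range -0.365 to 0.84). In slr-1 6 h, AUR1 was 2e-04 (range -0.42 to 2e-04) and AUR3 0.24 (range -1.17 to 0.24) without slr-1 0 h replicate 1.

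Some genes that had not passed did so elsewhere. In mock against 0 h, IAA29 was 0.84 (adjusted p = 0.0481) without Col-0 0 h replicate 2, and with quantile normalization GH3.3 (0.0146) and GH3.5 (0.0455) passed, GH3.5 also with only its own groups (0.0498). In Col-0 6 h against 2 h, LBD29 (0.0352) and LBD16 (0.028) passed with only their own groups, and LBD16 also with median centring (0.0483) and without slr-1 0 h replicate 1 (0.042) or replicate 2 (0.0424), range 0.042 to 0.33. In slr-1 6 h against 2 h, LBD16 passed with median centring (-0.73, adjusted p = 0.0476).

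For the 314 named results past the threshold, 2724 repeats in other settings gave the same call and 71 lost it, and 4150 and 246 did so with single arrays left out. For the 76 lists past the threshold, 757 gave the same call and 76 lost it in other settings, 57 of these with an estimated correlation, and 1029 and 35 did so with single arrays left out.

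The retained response in slr-1 at 6 h, selected on 1 replicate number and measured on the other, was 0.37 for higher genes (0.29 in the main analysis) and -0.35 for lower ones (-0.23). Median centring put the share of higher calls at 44.1% instead of 56% in slr-1 6 h and at 23% instead of 38.1% in slr-1 6 h against 2 h, and turned the balance of the response at 6 h (47.3% instead of 54%), while the median of all probe sets moved by -0.08 at most.

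With the replicate number as a replicate block the counts were 2564, 7150, 6716 and 707 for Col-0 2 h, Col-0 6 h, 6 h NAA against mock and mock against 0 h, 1789 and 2061 for slr-1 2 h and 6 h, 435 and 3978 for the response at 2 h and 6 h, 1928 at 0 h, 4822 and 173 for 6 h against 2 h in Col-0 and slr-1, and 3286 for the joint test. It ended 1 list call and 4 calls of named genes and changed no other. Deviations of arrays with the same number correlated at -0.16 to 0.13 over 21 pairs of groups (median 0.01). Over all probe sets no shared effect of the number was seen, which does not exclude one on some transcripts. Plastid-encoded transcripts had a higher mean log2 level on replicate 1 than 2 in Col-0 6 h NAA (11.08 and 10.45) and mock (11.57 and 10.79). The same held in slr-1 0 h (10.76 and 9.97), but not in slr-1 2 h NAA (10.40 and 10.59).

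Low signals limit what can be seen: changes of genes with signals near the added value of 18.9 depend on it, and probe sets under 218.1 in every group were not tested.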

Other observations

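Of the tests in this part, those on RNA quality and on green tissue were chosen only after the result was seen, as were the lists they use. Nuclear genes of photosynthesis stood lower in slr-1 before any NAA (adjusted p = 1.86e-14, adjusted p = 0.0494 with an estimated correlation) and fell in Col-0 after 2 h (adjusted p = 2.87e-08, adjusted p = 0.223 with an estimated correlation) and 6 h of NAA (adjusted p = 4.02e-09, adjusted p = 0.174 with an estimated correlation). At 6 h of NAA 6 of 18 genes were higher in slr-1, 0 were lower and 12 did not pass, with a median difference of 0.32 and no list test. Over 18 genes the mean log2 level was 11.03 ± 0.05 in Col-0 at 0 h, 10.13 ± 0.04 at 2 h, 9.06 ± 0.14 at 6 h of NAA and 10.77 ± 0.15 after mock, against 9.90 ± 0.06, 9.42 ± 0.06 and 9.50 ± 0.08 in slr-1 (n = 2 each). BCAT4 had a signal of 22386 ± 622 in slr-1 at 0 h against 1395 ± 775 in Col-0, and in Col-0 it fell to 205 ± 83.9 by 6 h of NAA.

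Plastid-encoded transcripts were lower as a list in slr-1 at 0 h (12 of 65 lower, median -0.50, limma camera adjusted p = 1.03e-04, adjusted p = 0.757 with an estimated correlation). This depended on slr-1 0 h replicate 2, whose GAPDH ratio of 1.16 stood apart, since without that array the median was -0.11. RNA quality of that array is a candidate explanation, but leaving the array out shows only the dependence and not its cause. In Col-0, replicate 2 had a lower mean log2 level of these transcripts than replicate 1 too, at 0 h (10.86 against 11.18) and after mock (10.79 against 11.57). In slr-1 2 h NAA it was higher (10.59 against 10.40). Less green tissue in the slr-1 segments is another candidate explanation, since nuclear photosynthesis genes were lower too (median -1.11). With NAA, where no array had a GAPDH ratio apart from the others, the median difference was -0.56 at 2 h, which that array does not explain, but only -0.15 at 6 h (0 of 65 past the threshold at each time). RNA quality and less green tissue do not exclude each other, and a measure of plastid number in the segments would be a test.

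A fall of the glucosinolate pathway with NAA in Col-0 may be read from BCAT4 (-4.66, adjusted p = 6.01e-06) and AT2G31790 (-4.65, adjusted p = 1.61e-07) in 6 h NAA against mock, genes singled out here after their values were seen. Only GSTU20 (-1.17, adjusted p = 0.0494) and UGT74B1 (-1.81, adjusted p = 2.48e-05) of the other pathway genes were tested against mock, with a median of -1.49. Part of this was a rise in mock: against 0 h, mock was higher for BCAT4 (2.06, adjusted p = 0.0328), AT2G31790 (1.69, adjusted p = 0.0124) and UGT74B1 (0.97, adjusted p = 0.0286), while GSTU20 did not pass there (1.58, adjusted p = 0.0628) or in 6 h NAA against 0 h (0.42, adjusted p = 0.474). With 2 genes a fall of the whole pathway cannot be told apart from a fall of single genes.

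LEA4-5 peaked in slr-1 at 2 h, at 2826 ± 1404 against 108 ± 53.7 at 0 h and 268 ± 50.4 at 6 h. The fall from 2 h to 6 h (-3.23, adjusted p = 0.00542) was not called without slr-1 2 h NAA replicate 1 (0.068) or slr-1 6 h NAA replicate 2 (0.0509), with a range of 0.00449 to 0.068. Dehydration during transfer could raise such a gene, and the median of 6 other dehydration genes at 2 h was -0.37, under the bound of 0.2 set in advance. By the rule set in advance such a median counts against a rise of these genes as a group. It met the bound by less than the spread of the genes (SD 1.06), but weighing the bound against that spread was not part of the rule. LTI30 (1.52) and COR47 (1.44) were higher and XERICO (-0.78) and DI21 (-0.61) lower, so a common rise cannot be told apart from changes of single genes. Mock arrays of slr-1 at 2 h would be a test.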
